A study of Mus musculus with 42 samples.

How the data were processed

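Single-cell RNA was measured in 24 libraries, 12 with GDF9 and 12 controls, and bulk 3' RNA in 18 libraries, 9 with GDF9 and 9 controls. The single-cell libraries were made with the 10x Chromium 3' v2 chemistry, and the bulk libraries were QuantSeq FWD libraries read on a NextSeq 500, per the labels. The deposited single-cell matrices hold raw UMI counts for 27998 features and the barcodes of each library. The deposited bulk table holds raw counts for the same number of features. STAR, Cell Ranger and the mm10 build are named, per the submitters' processing notes, with no versions and no statement of which tool made which table. How bulk reads were counted, and whether duplicates were removed, is not stated. Gene symbols and Ensembl identifiers came from the single-cell matrices, and 121 features share a symbol with another. Coordinates are those of GENCODE M21 on GRCm38 (mm10). Reads of Pou5f1 and Sox2 may include transgene RNA, which the counts cannot separate.

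The groups, comparisons, tests, gene lists, marker lists and rule for named genes were fixed before the data were examined. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs, and 35520 barcodes were removed for low UMIs and 1109 for mitochondrial share. Over all pairs of libraries, at most 3.12% of the smaller library's barcodes were shared. Scrublet ran on each library through scanpy (version 1.11.5) with an expected rate of 6%. Its automatic threshold marked 217 cells (0.363%) and was judged to have failed. No cells were removed as doublets in the main analysis, and removal of the 3584 cells with the highest scores was tried instead. Free RNA in the droplets was not subtracted, so class shares and levels within a class may carry RNA of other cells.

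Counts were tested with edgeR (version 4.0.16) by its quasi-likelihood F test, two-sided, with TMM scaling, the filterByExpr filter and a Benjamini-Hochberg FDR of 0.05. For single cells the UMIs were summed per library, over all kept cells or over the cells of 1 class, and the library was the replicate. The comparisons were GDF9 against control over all libraries, within each R number from a fit with 8 groups, and within classes that had at least 8 libraries of each arm with at least 20 cells. The test for a difference between R numbers was the interaction in the fit with 8 groups. For bulk, 11238 of 27998 features were tested in 1 fit of all 18 libraries. Each dose was compared with the controls of its number, the response at 1.0 was compared with that at 0.1 µg/ml, and the controls numbered 1.0 were compared with those numbered 0.1. DESeq2 (version 1.42.0) was the second tool. Log2 fold changes carry the standard error of the fit, and CPM values are means with SD. A fold against an arm with no counts was given as a lower limit from a floor of 3 counts over the group.

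The 27 gene lists held 403 genes and were tested with limma camera (version 3.58.1), two-sided, with a preset correlation of 0.01 and, as an alternative, an estimated correlation. The p-values were adjusted over the lists of a comparison. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. Class shares were compared by two-sided permutation with 100000 resamples, adjusted over 6 classes. Seeds were fixed.

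Clusters were made with leidenalg (version 0.10.2) from 2000 variable genes, 30 principal components and 15 neighbours. The resolution was 1.0, with 0.5 and 2.0 as alternatives. A marker counted as enriched when it was detected in at least 10% of a cluster's cells at a log2 fold of at least 1.0 over the median cluster of its technical set. A cluster took the name of the class with the largest share of enriched markers, if these were at least 3 and at least 1 in 3 of the class's markers. The share also had to exceed that of the next class by a factor of 1.5, unless at least 2 of the cluster's 10 top genes were markers of the class and fewer were markers of any other. Clusters with more top genes from another class, and shallow clusters with no top gene of their own class, stayed unnamed. Of 45 clusters 33 were named, and unnamed clusters were left out of the classes.

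Several choices were made after the data were seen. The 3 technical sets came from average linkage of the libraries on 329 genes with at least 50 CPM and at most a 2-fold range between the cell clusters of R4, without use of the arm. They were described with 69 genes with transcripts under 1000 bp and 99 with transcripts over 3000 bp, lengths being known for 98.7% of genes. Clusters were then made separately in each set. The naming rule was revised after a first look at the clusters and again later, when the epithelial and keratinocyte classes were joined. An earlier version had by then printed class shares per library and arm. The doublet alternative, the setting without GDF9 R3_C1, GDF9 R3_C3 and control R3_C1, and the setting without the 3 bulk libraries under 400000 counts were also chosen then. The number of random splits per class was raised to 40 after 20 had been seen and then to 100 after 40 had been seen, and that for the difference between R numbers was lowered to 30 for run time after 50 had been seen. The tests of explanations had their predictions written before they ran, apart from the random splits, whose predictions were written afterwards.

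Genes were named by rule. For the all-cell and the 1.0 µg/ml comparisons these were the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 10 CPM. They also had to share a direction in all R numbers, or not overlap between groups in bulk. The 3 members with the smallest p of each list, and a fixed set of 12 genes such as Nanog and Id1, were added. Some genes that the rule names are not reported here. Other comparisons used the 5 largest rises and falls. Predicted genes, mitochondrial and ribosomal protein genes and pseudogenes were left out of the top genes. Genes named outside the rule are said to be so.

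The edgeR steps were tested on simulated data with 200 changed genes. For the all-cell comparison (14093 genes) 61.6% of 2-fold and 94.9% of 4-fold changes were recovered, with 3.7% false calls. For the fit by R number (15774 genes) the values were 12.2%, 66.3% and 3.8%, and for pluripotent-like cells (10105 genes) 75.0%, 98.0% and 4.4%. For bulk at 1.0 µg/ml (11238 genes) 1.1% of 2-fold and 29.3% of 4-fold changes were recovered with 3.2% false calls. DESeq2 gave 20.4% false calls there and 8.7% in the all-cell comparison.

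Whether R and C numbers pair a GDF9 library with a control was checked by correlating the libraries' deviations from their group means across genes. Not every correlation was over 0.1, so no pairing was used in the main fits. The outlier test needs groups of 4 to 10 libraries, and there were 0 such groups. Alternatives covered scaling, filters, tools, cell filters, doublets, cluster resolution, the unit of replication and the leaving out of libraries. The colony counts were not analysed here. Python (3.11.15), numpy (2.4.6), scipy (1.17.1), pandas (2.3.3), anndata (0.12.19), matplotlib (3.10.9) and R (4.3.3) were used.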

Results

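Expression was measured at day 15 of reprogramming in secondary mouse embryonic fibroblasts of the B6;129 strain, which carry inducible Oct4, Klf4, Sox2 and Myc (OKSM). The cells were kept in serum and received either recombinant GDF9, a growth factor of the TGF-beta family, or its carrier (the control). The labels give the share of pluripotent cells at day 15 as the quantity of interest. They name Oct4-EGFP colonies, bulk RNA and single-cell RNA as its readouts, and the colony counts were not analysed here. There were 24 single-cell libraries, 12 with GDF9 and 12 controls, numbered R1 to R4 and C1 to C3. There were 18 bulk 3' libraries: 3 with GDF9 at each of 0.1, 0.5 and 1.0 µg/ml, and 3 controls carrying each of these dose numbers. The labels do not define R and C and give no dose for the single-cell libraries. They describe biological triplicates and separate replicates for each assay. The p-values for single genes and class shares measure the spread between libraries, or between R numbers where these were the unit. Those for gene lists with a preset correlation compare the genes of a list with the other genes.

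The series description states about 50000 cells, and the single-cell matrices hold 96680 barcodes. Of these, 59745 cells (61.8%) were kept, 39340 with GDF9 and 20405 controls. Total UMIs per GDF9 library were 19260395 to 66722919 in R1, 14225373 to 26053923 in R2, 4146736 to 13624954 in R3 and 21501113 to 25169478 in R4. The controls held 8937713 to 17187936 in R1, 2016412 to 4295147 in R2, 11272187 to 12793880 in R3 and 18737413 to 21152284 in R4. Kept cells per library ran from 686 to 4886 and their median UMIs from 1276 to 11994. The 6 libraries with the lowest median UMIs per barcode were control R3_C1 (571, with 15.7% of barcodes kept), GDF9 R3_C3 (620, 20.4%), control R2_C1 (699, 26.7%), control R2_C3 (856, 40.8%), GDF9 R3_C1 (922, 42.8%) and control R2_C2 (1054, 53%). Bulk totals with GDF9 were 1427907 to 3663471 counts at 0.1 µg/ml, 37046 to 1273024 at 0.5 µg/ml and 369576 to 2926142 at 1.0 µg/ml. Bulk control totals were 1894556 to 4690745, 876946 to 3017935 and 88391 to 1365844 for the same dose numbers. The annotated long non-coding RNA Gm42418 (chromosome 17, 39846958 to 39848788) took 10.4% to 24.1% of the bulk counts. Intervals and floors of counts cover counting error only.

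The single-cell libraries fell into 3 technical sets on 329 genes that differ little between clusters of cells. Short transcripts exceeded long ones by 1.89 to 2.62 on the log2 scale in set T1, by 0.62 to 1.41 in T2 and by 0.86 to 1.24 in T3. T1 held 6 GDF9 libraries and 1 control, T2 held 6 GDF9 libraries and 8 controls, and T3 held the 3 controls of R2 alone. All 3 GDF9 libraries of R2 lay in T1, so in R2 the set and the treatment cannot be told apart. R4 lay wholly in T2. T2 is the set with enough libraries of both groups for a test, and its class shares and counts of genes are given beside the pooled ones.

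The first comparison was of the cell classes present at day 15. The pluripotent-like share of cells was higher with GDF9, at 37.1% ± 18.4 (SD, n = 12) against 21.0% ± 14.7 in controls. These cells were recognised by genes of the pluripotent state such as Nanog and Dppa5a. The permutation test gave p = 0.0247 after adjustment over 6 classes, and 11 of 12 GDF9 libraries lay above the control median. Within T2 the shares were 36.6% and 16.1%. R2 went the other way, with 34.2% ± 6.97 (n = 3) against 39.7% ± 6.04. R1 had 21.3% against 4.85%, R3 had 59.2% against 25.2% and R4 had 33.7% against 14.3%. Without GDF9 R3_C1, GDF9 R3_C3 and control R3_C1 the difference was 8.61 percentage points (permutation p = 0.126 after adjustment).

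Trophoblast-like cells, marked by placental genes such as Tpbpa and Ctsq, fell to 6.37% ± 4.87 (SD, n = 12) from 25.4% ± 17.0. All 12 GDF9 libraries lay below the control median, and the share was lower in each R number: 2.03% against 13.1% in R1, 4.18% against 19.0% in R2, 10.4% against 38.2% in R3 and 8.83% against 31.5% in R4. The R3 means rested on single libraries (SD 7.44 with GDF9 and 30.9 in controls, n = 3): control R3_C1 had 73.8% against 19.7% and 21.0% in the other controls, and GDF9 R3_C3 had 19.0% against 6.75% and 5.56%. The permutation p of 1e-05 was the smallest that the permutations can give, and it was 6.0e-05 after adjustment. Stromal-like cells, marked by collagens and other matrix genes, fell to 7.80% ± 2.90 from 21.2% ± 15.8 (adjusted permutation p = 0.00376). The difference was -36.3 percentage points in R1 and -5.08, -3.27 and -8.90 in R2, R3 and R4, and -5.75 without R1 (adjusted permutation p = 0.0467). Epithelial-or-keratinocyte-like cells fell to 7.44% ± 5.41 from 18.4% ± 9.69 (adjusted permutation p = 0.00356). That difference was -1.85 percentage points at a cluster resolution of 2.0 (adjusted permutation p = 0.547) and -3.77 with unnamed clusters counted by their leading markers (0.357), and R2 had 12.8% against 13.2%. Neural-progenitor-like cells, marked by genes such as Sox1 and Fabp7, rose to 14.2% ± 10.9 from 1.73% ± 2.42 (adjusted permutation p = 0.00096). Neuron-like cells, marked by genes such as Stmn2 and Nefl, rose to 7.50% ± 4.64 from 0.998% ± 1.57 (adjusted permutation p = 0.00033). GDF9 libraries past the control median numbered 12 of 12 for stromal-like, 11 of 12 for epithelial-or-keratinocyte-like, 9 of 12 for neural-progenitor-like and 11 of 12 for neuron-like cells. All these tests were two-sided.

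Within T2 the trophoblast-like shares were 8.27% and 28.9%, the stromal-like shares 8.64% and 22% (exact permutation p = 0.0856 after adjustment, not past the threshold) and the epithelial-or-keratinocyte-like shares 5.08% and 18.5%, with GDF9 and in controls. The neural-progenitor-like shares were 18.1% and 2.58% and the neuron-like shares 7.14% and 1.46%. R3 went the other way for neural-progenitor-like cells, with 0.165% against 4.25%. GDF9 R3_C1 and R3_C2 had 0 of 1688 and 0 of 1692 cells in this class. Unnamed clusters held 41.8% of the cells of GDF9 R3_C2, so the R3 reversal may depend on the naming. No cell of the R2 controls was in a neural class, where 0 of 686, 1819 and 1026 cells allows shares of up to 0.437%, 0.165% and 0.292%. No cluster of T3 was named for a neural class, so these zeros depend on the naming. Unnamed clusters held 19.6% ± 9.47 of GDF9 cells and 11.3% ± 5.90 of control cells (SD, n = 12). With R numbers as the unit, 4 against 4, no share passed the threshold, where the smallest exact p possible is 0.0286 before adjustment over 6 classes, and the adjusted exact permutation p was 0.0857 for trophoblast-like and 0.200 for pluripotent-like cells.

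**Figure D1:**
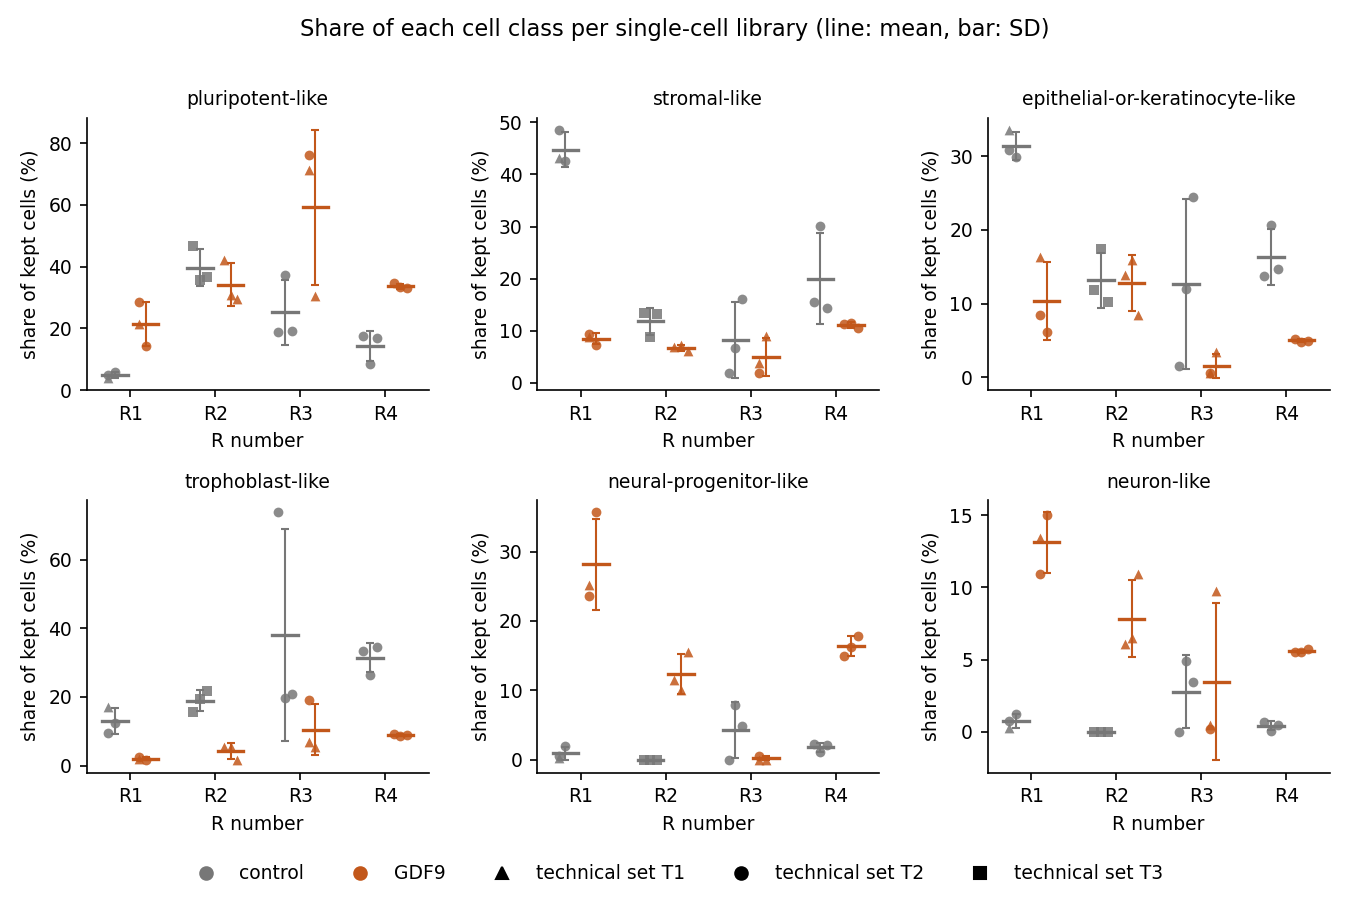
Share of kept cells (%) in each of 6 cell classes, per single-cell library, by R number and treatment (points: libraries, with the marker giving the technical set; line: mean; bar: SD, n = 3). Trophoblast-like cells were lower with GDF9 in each R number, at 2.03% to 10.4% against 13.1% to 38.2%, and pluripotent-like cells were not higher with GDF9 in R2.

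The second comparison summed the UMIs of all kept cells of a library, which reads composition and regulation together. Foxa2, a transcription factor of floor plate and endoderm (ENSMUSG00000037025, GRCm38 chromosome 2, 148042877 to 148046969), rose to 11.6 ± 6.89 CPM (counts scaled to the library total; SD, n = 12) from 0.284 ± 0.278. Its log2 fold change of 5.79 ± 0.44 (SE) had an FDR of 5.0e-09. The hormone precursor gene Trh (ENSMUSG00000005892, chromosome 6, 92242061 to 92244650) rose to 20.5 ± 16.6 CPM from 1.41 ± 1.05, by 4.06 on the log2 scale, and 12 of 12 GDF9 libraries lay above the control median. The cathepsin gene Ctsq of the placenta (ENSMUSG00000021439, chromosome 13, 61035024 to 61040631) dropped to 4.03 ± 6.94 CPM from 54.3 ± 45.3, with a log2 fold change of -3.88. Nanog, of the pluripotency network (ENSMUSG00000012396, chromosome 6, 122707489 to 122714633), rose to 149 ± 74.3 CPM from 87.5 ± 55.3 with an FDR of 0.0441.

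Of 14093 genes tested with edgeR, 6395 passed an FDR of 0.05 in the single-cell libraries, 2949 up and 3446 down. In T2 alone 5909 passed, and the 4468 genes called in both fits all had the same sign. With UMIs summed per R number, 4 against 4, the count was 1334, and 3141 when R was also a block. Without GDF9 R3_C1, GDF9 R3_C3 and control R3_C1 6705 passed. With library size alone as the scaling, 1627 rose and 4324 fell, and the median log2 fold change of all genes moved by -0.23. All changes are relative to the TMM scaling. The largest rises by the fixed rule were Trh, Pomc, Spink1, Fabp7, Pantr1, Cartpt, Stmn3, Nnat, Crmp1 and Gng3, with log2 fold changes from 4.06 down to 2.86. The largest falls were Ctsq, Cxcl5, Lum, Prl7a1, Prl2b1, Upk3b, Tpbpb, Pappa2, Ctsr and Ctsj, from -3.88 to -2.95. In T2 the log2 fold changes of Spink1, Fabp7 and Pantr1 were 7.01, 1.82 and 1.78, against 3.72, 3.44 and 3.36 over all libraries, and Cartpt did not pass (1.57, FDR 0.153). Pou5f1, Sox2, Zfp42 and Dppa5a rose by 1.03, 1.27, 1.40 and 1.87 on the log2 scale. In T2 the FDR was 0.0546 for Zfp42 and 0.180 for Dppa5a. Col1a1 and Epcam dropped, with log2 fold changes of -2.07 and -0.83. Of 3 direct targets of BMP or TGF-beta signalling, none passed: Id1 (log2 fold change -0.10), Id3 (-0.14) and Smad7 (-0.34). Gdf9 itself stayed below 1 CPM in each arm of each R number and was not among the genes tested over all cells.

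Gene lists fixed before the data were examined were tested with limma camera, two-sided, with a preset correlation. In the all-cell comparison of the single-cell libraries 14 of 25 measured lists passed, and none passed with an estimated correlation. Of 25 pluripotency genes measured, 23 rose and none fell (camera adjusted p = 1.3e-08; adjusted p = 0.198 with an estimated correlation), and 23 rose when adjusted over the list alone. Lin28a, Dnmt3l and Tdh were among them, with log2 fold changes of 1.97, 1.68 and 1.62. Neural progenitor genes rose in 12 of 13 (13 when adjusted over the list alone; adjusted p = 1.4e-07), with Sox21 at 2.34 and Msi1 at 1.99. All 11 neuron genes rose (11 when adjusted over the list alone; adjusted p = 1.4e-07), with Gap43 at 2.74 and Ina at 2.93. The estimated-correlation p was 0.109 for progenitors and 0.114 for neurons. The list of primed pluripotency and mesendoderm rose in 5 of 6 genes (5 when adjusted over the list alone; adjusted p = 0.00106; 0.109 with an estimated correlation), among them Otx2, Fgf5 and Dnmt3b.

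Trophoblast genes fell in 16 of 20 and rose in 1 (19 down and 1 up when adjusted over the list alone; adjusted p = 6.9e-07; 0.181 with an estimated correlation). Elf5, Gata2 and Prl2c2 were among the falls, with log2 fold changes of -1.83, -1.65 and -2.40. Stromal matrix genes fell in 18 of 25 (20 when adjusted over the list alone; adjusted p = 7.7e-05; 0.425 with an estimated correlation), including Pdgfra, Twist2 and Thy1. Epithelial genes fell in 17 of 21 (19 when adjusted over the list alone; adjusted p = 1.5e-07; 0.109 with an estimated correlation), including Krt19, Dsp and Spint1. Contractile genes fell in 6 of 11 (adjusted p = 0.0721) and keratinocyte genes in 2 of 8 (0.792), so neither list was called. The same numbers passed when adjusted over the list alone.

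Most of the listed proliferation genes rose. Of 20 S-phase genes 15 rose (15 when adjusted over the list alone, camera adjusted p = 3.5e-07), including Dtl, Uhrf1 and Pcna. Of 20 G2/M genes 17 rose (20 when adjusted over the list alone; adjusted p = 3.0e-08), including Cenpf, Ube2c and Tpx2. With an estimated correlation the camera adjusted p-values were 0.150 and 0.109, so neither list held. Interferon-response genes fell in 10 of 14 (10 when adjusted over the list alone; adjusted p = 1.1e-05; 0.109 with an estimated correlation), with Irf7 at -1.84, Ifit3 at -2.38 and Ddx58 at -0.92. Immediate-early and stress genes fell in 10 of 13 (11 when adjusted over the list alone; adjusted p = 2.1e-05; 0.123 with an estimated correlation), among them Zfp36, Atf3 and Hspa1a. The lists of p53 targets (8 of 14 down; adjusted p = 0.0319), secretory and senescence genes (10 of 15 down, 12 when adjusted over the list alone; 0.0140) and skeletal muscle (4 of 8 up, 1 down; 0.0478) were also called. Their estimated-correlation values were 0.459, 0.464 and 0.201, and 8 p53 targets and 4 rises and 1 fall of the muscle list passed when adjusted over the list alone.

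TGF-beta and SMAD2/3 targets went both ways, with 3 up and 9 down of 19 (3 and 10 when adjusted over the list alone; adjusted p = 0.147). Snai1 was among the falls, with a log2 fold change of -1.54. BMP and SMAD1/5 targets had 3 up and 4 down of 13 (adjusted p = 0.941), and their median was below 0 while their mean was above it. Receptors and SMADs of the GDF9 pathway had 1 up and 3 down of 11 (0 and 3 when adjusted over the list alone; adjusted p = 0.158), with Tgfbr2 at -1.20, Smad2 at -0.66 and Bmpr2 at -0.56. No call was made for hypoxia and glycolysis (5 up and 1 down of 14, and 4 and 1 when adjusted over the list alone; adjusted p = 0.147), cholesterol synthesis (3 up and 1 down of 12; 0.158), macrophage (1 up and 2 down of 4; 0.147), endothelial (1 up and 4 down of 7; 0.0787), glia (1 up and 2 down of 5; 0.941) or extraembryonic endoderm genes (1 up and 2 down of 6; 0.941). The median of the last list was below 0 and its mean above. The cholesterol, macrophage, endothelial, glia and extraembryonic endoderm counts were the same when adjusted over the list alone. Too few members of the lists of 2-cell-like and erythroid genes were measured here. In the fit by R number they had 3 and 1 measured members and were not called (adjusted p of 0.753 and 0.464 in R1).

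The third comparison was made within each R number, since R may mark an independent experiment. The fit with 8 groups called 5657 genes in R1 (2625 up, 3032 down), 6755 in R2 (3099 up, 3656 down), 2346 in R3 (1269 up, 1077 down) and 2394 in R4 (1290 up, 1104 down). With only the 6 libraries of the R number in the fit the counts were 3133, 7751, 10 and 7597, so the counts for R1, R3 and R4 depended on the fit. In all 4 numbers 607 genes passed in the same direction, 178 up and 429 down, among them Foxa2 and Ctsq. R1 and R4 shared 2094 called genes, and 0 of their shared calls had opposite signs. Pluripotency genes rose in 22 of 25 in R1, 11 in R2, 12 in R3 and 10 in R4, and trophoblast genes fell in 19, 11, 11 and 10 of 20. Adjusted camera p-values for pluripotency were 5.4e-12, 0.00480, 8.9e-07 and 3.8e-10, and none held with an estimated correlation. The primed and mesendoderm list and the interferon list held with an estimated correlation in R1 (adjusted p = 0.00232 and 0.0365) and in R4 (0.00494 and 0.0261).

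The test of the difference between the R numbers called 3142 of 15774 genes, and 2362 of them had fitted changes of both signs among the R numbers. The Oct4 gene Pou5f1 rose by 1.75, 1.76 and 1.22 in R1, R3 and R4 on the log2 scale and had a log2 fold change of -0.31 in R2. Its level was low, at 3.43 ± 0.921 CPM with GDF9 and 1.09 ± 0.488 CPM in controls of R1 (SD, n = 3). Id3, a direct target of BMP signalling, rose by 1.90 in R2 (FDR 0.00213) and did not pass in R1, R3 or R4 (-0.79, -0.75 and -0.21). Smad7, an inhibitor of TGF-beta signalling, had a log2 fold change of -1.37 in R2 (FDR 0.00118). Without R2 the test called 1 gene and in T2 alone it called 10, so the count rested on R2, where set and treatment cannot be told apart. The R3 count was 693 without GDF9 R3_C1, 1213 without GDF9 R3_C2, 5116 without GDF9 R3_C3, 1331 without control R3_C1 and 735 without control R3_C3. The R4 count lay from 1068 (without control R4_C2) to 1384 (without control R4_C1) when any of its 6 libraries was left out: 1236 without GDF9 R4_C1, 1132 without GDF9 R4_C2, 1155 without GDF9 R4_C3 and 1304 without control R4_C3.

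**Figure D2:**
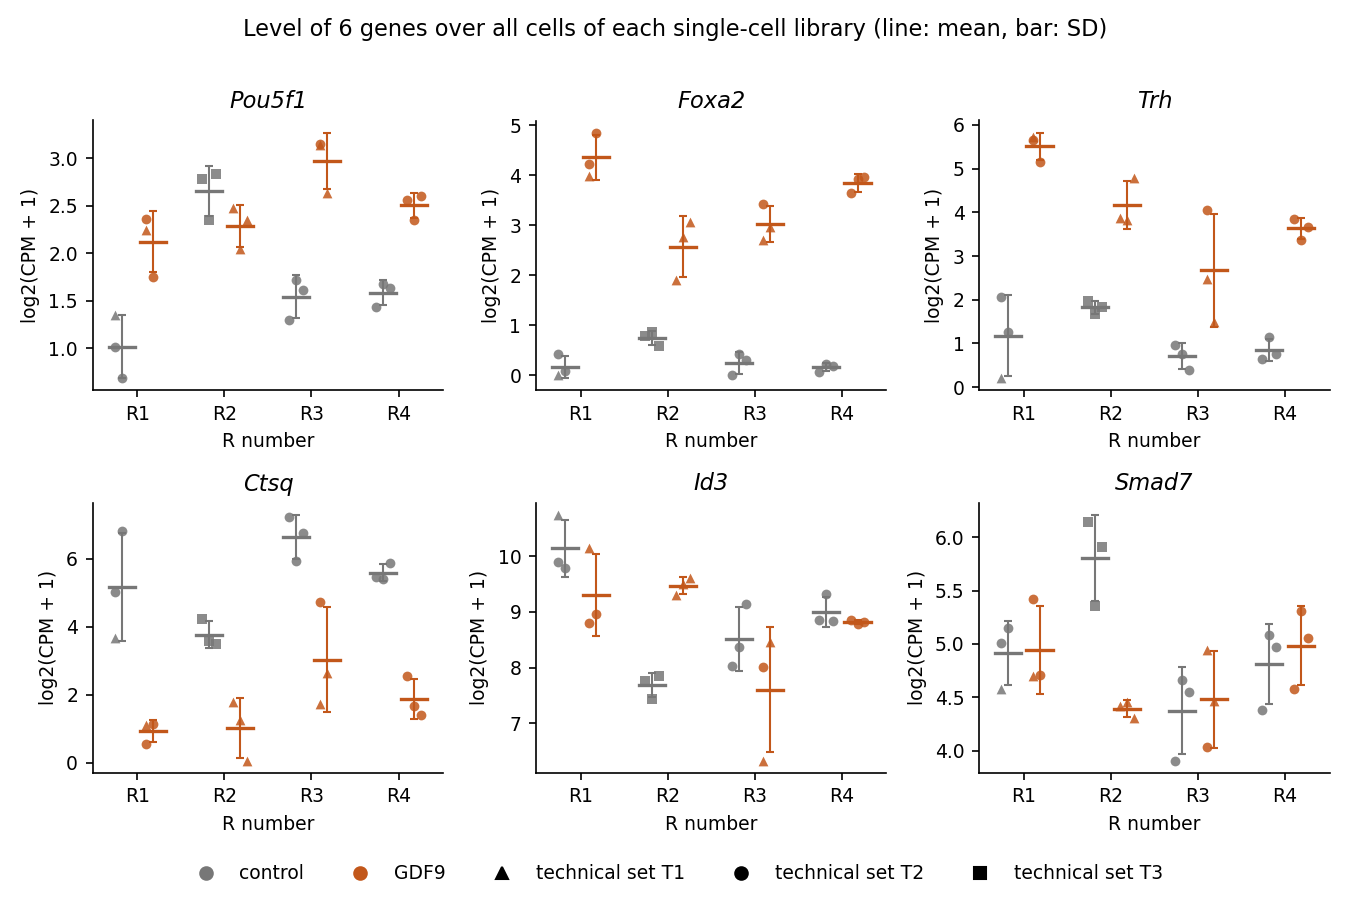
Level of 6 genes, as log2 of CPM plus 1, over all kept cells of each single-cell library, by R number and treatment (points: libraries, with the marker giving the technical set; line: mean; bar: SD, n = 3). Foxa2 and Trh were higher and Ctsq lower with GDF9 in each R number, while Id3 was higher and Smad7 lower with GDF9 in R2 alone.

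The fourth comparison was made inside a cell class, to separate it from shifts in class shares. Within pluripotent-like cells (12 against 12 libraries), Nnat, an imprinted gene of the developing brain, rose to 22.2 ± 14.6 CPM (SD) from 3.30 ± 3.87, by 2.70 on the log2 scale (FDR 0.00671). Fabp7 rose by 2.76 (FDR 0.0480) and did not pass in T2 (FDR 0.420). Free RNA was not subtracted, and the neural classes held a larger mean share of GDF9 cells than of control cells. Whether free RNA contributed to these rises, or to other rises of neural genes within classes below, was not tested. Nanog did not change detectably (log2 fold change -0.22, FDR 0.441), and neither did Pou5f1 (0.11), Sox2 (0.21) or Dppa5a (0.67). These genes are among the markers that named the class, so their levels within it were partly set by that choice. In this class edgeR called 54 genes (20 up, 34 down), 1872 had an unadjusted p below 0.05 and DESeq2 called 368. In T2 alone 8 genes passed. In T2 this class was made up of clusters T2.1, with 13.3% of GDF9 and 5.36% of control cells (exact permutation p = 0.0186), T2.5, with 12.9% and 2.92% (0.608), and T2.3, with 10.4% and 7.83% (0.636).

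Few single members of the trophoblast list passed inside a class. The trophoblast list had 2 of 16 members down in pluripotent-like cells (8 down and 1 up when adjusted over the list alone; camera adjusted p = 3.0e-05) and 3 of 13 in stromal-like cells (10 when adjusted over the list alone; adjusted p = 1.4e-06). In epithelial-or-keratinocyte-like cells 4 of 16 fell (5 when adjusted over the list alone; adjusted p = 0.0537). In trophoblast-like cells, which these genes named, 1 of 19 fell (3 when adjusted over the list alone; adjusted p = 0.0280). With an estimated correlation the adjusted p-values were 0.222, 0.165, 0.504 and 0.270. Two-sided camera calls held with an estimated correlation for neural progenitor genes in pluripotent-like cells (1 of 6 up; adjusted p = 0.00402; 0.0322 with an estimated correlation) and for neuron genes in epithelial-or-keratinocyte-like cells (3 of 3 up; adjusted p = 1.2e-05; 0.00452).

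In stromal-like cells (12 against 12 libraries) edgeR called 64 genes, 5 up and 59 down, and 36 in T2. Nnat, Mylpf, Uchl1 and Nasp rose by 1.95, 1.84, 1.57 and 0.89 on the log2 scale. Prl3d1, Ctsj, Prl6a1, Plet1 and Clmp had log2 fold changes from -2.98 to -2.21. In epithelial-or-keratinocyte-like cells (11 against 12 libraries) 288 genes were called, 144 up and 144 down, and 166 in T2, where the class was 1 cluster. In T1 it was made up of T1.3, with 5.90% of the cells of 6 GDF9 libraries and 9.01% of the cells of 1 control, and T1.7, with 3.90% and 24.6%. Tnnt1, Bex2, Ly6h, Uchl1 and Ifitm1 rose by 3.43 to 2.15, and Ctsj, Prl7d1, Prl2a1, Gpa33 and Ifit3 had log2 fold changes from -2.99 to -2.09. In trophoblast-like cells (12 against 12 libraries) 62 genes were called, 33 up and 29 down, and 32 in T2. Fermt1, Slc39a2, Nkain4, Pomc and Doxl2 rose by 2.70 to 1.78, and Ctsq, Igfbp7, Fbln1, Pla2g4d and Ctsr had log2 fold changes from -2.84 to -1.90. DESeq2 called 165, 588 and 274 genes in these classes. The neural classes had too few control libraries with at least 20 cells for this test. Most of these counts moved when 1 R number was left out: without R4 pluripotent-like cells had 0 genes and trophoblast-like cells 0, stromal-like cells 14 and epithelial-or-keratinocyte-like cells 140.

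The fifth comparison was the bulk assay, with each dose against the controls that carry its number. At 1.0 µg/ml Foxa2, a floor plate and endoderm factor, stood at 82.7 ± 21.3 CPM (SD, n = 3), and all 3 controls had 0 counts. That is at least 57.9-fold higher, against a floor of 3 counts over the control group. Spink1, a secreted trypsin inhibitor (ENSMUSG00000024503, chromosome 18, 43728082 to 43737557), stood at 179 ± 54.0 CPM and was at least 126-fold higher. Sox2, shared by pluripotent and neural cells (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461), rose to 258 ± 135 CPM from 18 ± 17 (log2 fold change 3.76 ± 0.70, FDR 3.6e-04). The placental prolactin gene Prl2c2 (ENSMUSG00000079092, chromosome 13, 12996125 to 13005383) dropped to 146 ± 84.9 CPM from 4548 ± 1676, with a log2 fold change of -4.93 and an FDR of 3.3e-11. Nanog did not pass (log2 fold change 2.70, FDR 0.0717), nor did Pou5f1 (2.60, FDR 0.115).

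At 1.0 µg/ml edgeR called 743 of 11238 genes in the bulk libraries, 295 up and 448 down, and DESeq2 called 1067. The largest rises were all against controls at 0: Spink1, Foxa2, Cntn2, Otx2, Fgf4, Dmbx1, Nkx6-1, Dll3, Soga3 and Miat, at least 39.8-fold to at least 126-fold higher. The largest falls were Stat5a, Il17rb, Srpr, Efhd1, Irs3 and Slc6a12, with GDF9 libraries at 0 and at least 35.9-fold to at least 39.9-fold lower, and Ctsq, Hsd17b2, Osbp and Ctsr, with log2 fold changes from -7.10 to -5.91. These genes were chosen among those whose 3 GDF9 and 3 control libraries do not overlap, which chance gives in 10% of genes. Col1a1 dropped, with a log2 fold change of -1.38, and Dppa5a rose by 3.30. Id1 (-0.32), Id3 (-0.98), Smad7 (-0.97), Epcam (-0.56) and Zfp42 (1.77) did not pass. The count was 450 without control replicate 2 and 380 without control replicate 3.

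Of the 25 lists measured in bulk, 12 passed at 1.0 µg/ml. Pluripotency genes rose in 10 of 24 (14 when adjusted over the list alone; camera adjusted p = 1.2e-08; adjusted p = 0.115 with an estimated correlation). Neuron genes rose in 7 of 10 (10 when adjusted over the list alone; 5.4e-09; 0.0248), among them Ina and Elavl4. Primed and mesendoderm genes rose in 2 of 5 (3 when adjusted over the list alone; 9.3e-05; 0.0248) and G2/M genes in 9 of 20 (11 when adjusted over the list alone; 6.3e-09; 0.0248), including Birc5 and Top2a. Trophoblast genes fell in 13 of 19 (15 when adjusted over the list alone; 1.6e-14; 0.0248), including Prl3b1. These last 4 lists held with an estimated correlation. Neural progenitor genes rose in 2 of 11 (6 when adjusted over the list alone; adjusted p = 6.7e-06; 0.0759 with an estimated correlation) and S-phase genes in 4 of 20 (9 when adjusted over the list alone; 3.5e-05; 0.0739). Stromal matrix genes fell in 8 of 24 (13 when adjusted over the list alone; 1.6e-07; 0.115) and epithelial genes in 3 of 19 (5 when adjusted over the list alone; 0.0108; 0.115). Secretory genes fell in 5 of 15 (8 when adjusted over the list alone; 6.3e-04; 0.197), endothelial genes in 4 of 6 (0.0215; 0.190) and the interferon list in 1 of 13 (0.00343; 0.115). TGF-beta targets had 1 up and 2 down of 16, BMP targets 0 of 8 and GDF9 receptors and SMADs 0 of 11, and none of these lists was called.

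At 0.1 µg/ml edgeR called 0 genes, with 549 at an unadjusted p below 0.05, and DESeq2 called 0. Sox2 (log2 fold change 0.88) was within the spread between replicates. Leaving out GDF9 replicate 1 or 3 gave 1 gene. The keratinocyte and trophoblast lists passed with no single gene called (camera adjusted p = 2.5e-04 and 0.0290; 0.0668 and 0.796 with an estimated correlation). At 0.5 µg/ml edgeR called 108 genes, 24 up and 84 down, and DESeq2 called 308. Nnat rose to 554 ± 221 CPM (SD, n = 3) from 59.6 ± 26.3 (log2 fold change 3.30, FDR 3.8e-04), and Spink1 rose by 4.92. Bahd1 and Lsm1 had GDF9 libraries at 0 and were at least 28.4-fold and at least 24.6-fold lower. Trophoblast genes fell in 5 of 19 (camera adjusted p = 2.8e-05), and the neuron (2.8e-05), neural progenitor (0.0155), primed (0.00932) and G2/M (0.0297) lists were called up. None of these 5 held with an estimated correlation, where adjusted p ran from 0.179 to 0.576. The count was 22 without GDF9 replicate 1, 49 without GDF9 replicate 3, 37 without control replicate 1 and 57 without control replicate 2. It was 360 without the 3 libraries under 400000 counts, 1 of which is a GDF9 library of this dose with 37046 counts.

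The difference between the responses at 1.0 and 0.1 µg/ml was called for 151 genes, 56 up and 95 down. Spink1 and Otx2 were higher at 1.0 µg/ml, with FDRs of 0.00214 and 0.0303 for the difference. The count was 98 without GDF9 0.1 replicate 3, 90 without GDF9 1.0 replicate 1, 36 without control 0.1 replicate 1, 72 without control 0.1 replicate 2, 60 without control 1.0 replicate 2 and 53 without control 1.0 replicate 3. Controls carrying the number 1.0 differed from those carrying 0.1 in 1 gene, Tinagl1 (log2 fold change -3.21, FDR 0.0479), with 471 at an unadjusted p below 0.05. That call ended without control 0.1 replicate 1 or 3, or without any of the 3 controls numbered 1.0. In these controls the pluripotency list was lower (camera adjusted p = 0.0155) and the stromal list higher (9.0e-06), and both had 0.690 with an estimated correlation. Across genes, the log2 fold changes correlated with Spearman's rho of 0.111 between 0.1 and 1.0 µg/ml, 0.152 between 0.1 and 0.5 and 0.415 between 0.5 and 1.0, and genes are not independent replicates.

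**Figure D3:**
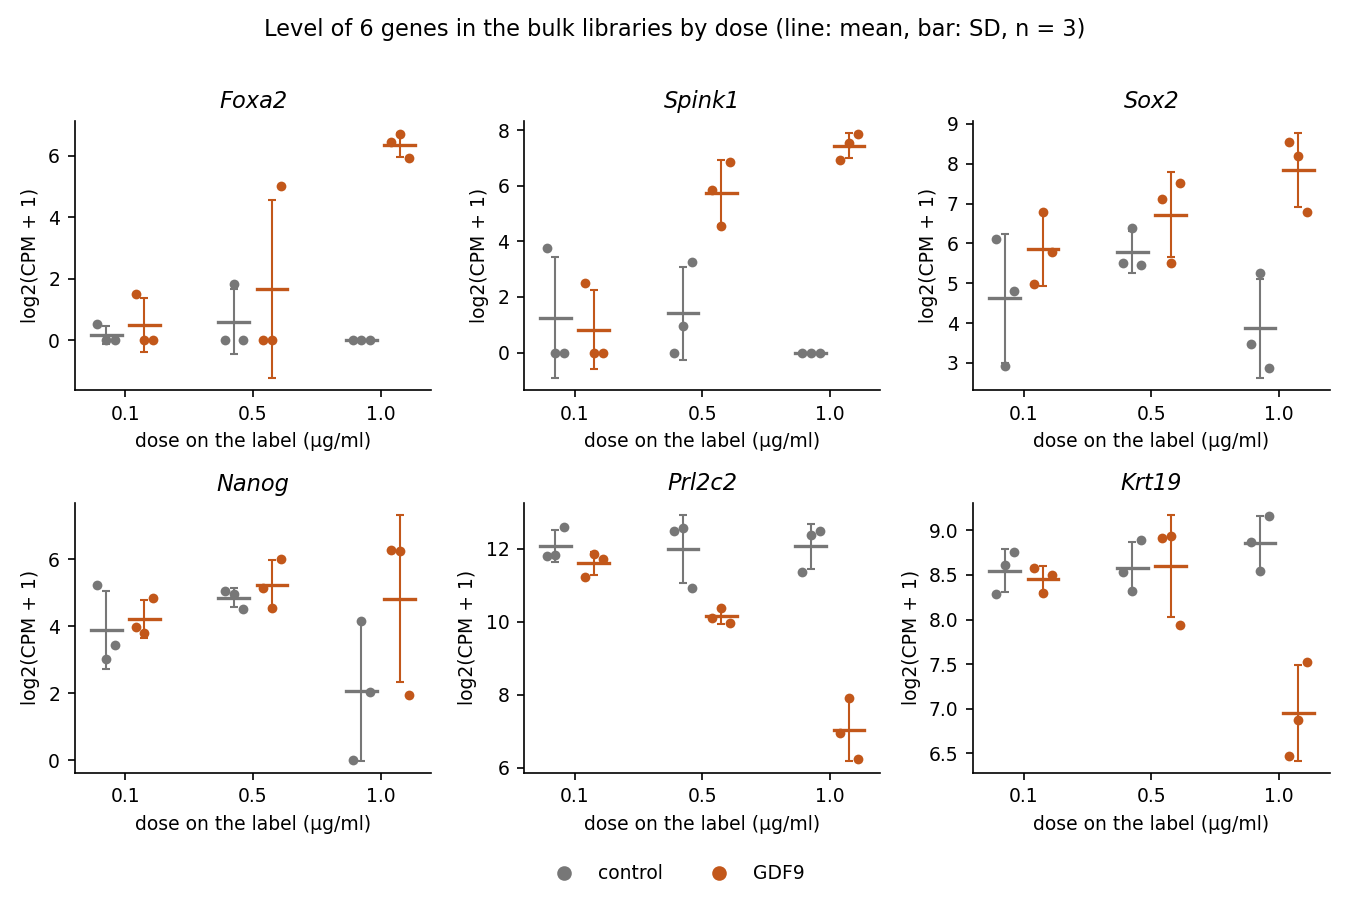
Level of 6 genes, as log2 of CPM plus 1, in the bulk libraries by the dose on the label (µg/ml) and treatment (points: libraries; line: mean; bar: SD, n = 3). At 1.0 µg/ml Foxa2 stood at 82.7 CPM and Spink1 at 179 CPM with controls at 0, and Prl2c2 stood at 146 CPM against 4548.

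The sixth comparison set the bulk contrast at 1.0 µg/ml beside the all-cell single-cell contrast, which share no libraries. Of 11050 genes tested in both assays, 601 were called in both, and all 601 had the same sign. If calls and signs were independent between the assays, 174 genes would be called in both with the same sign. Foxa2, Spink1, Sox2 and Otx2 rose in both assays, and Ctsq, Lum and Prl2c2 fell in both. Spearman's rho across genes was 0.595, and genes are not independent replicates. With T2 alone for the single-cell contrast, 592 of 592 had the same sign, with a rho of 0.618.

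**Figure D4:**
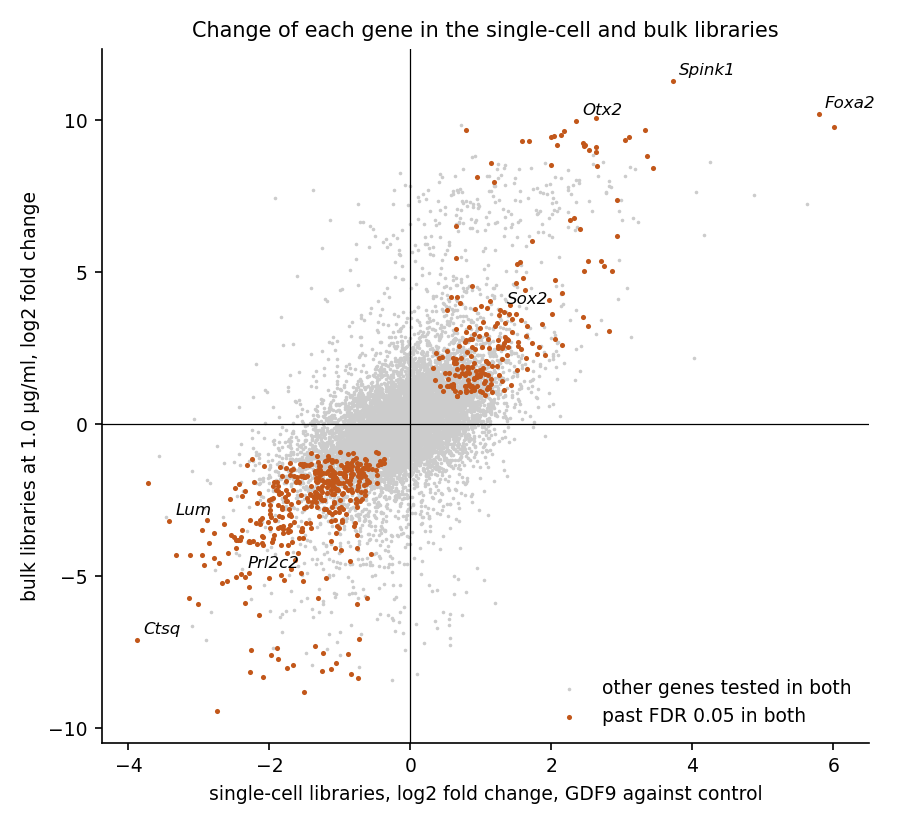
Log2 fold change of each gene with GDF9 in the single-cell libraries (horizontal axis, all kept cells, 12 against 12) and in the bulk libraries at 1.0 µg/ml (vertical axis, 3 against 3), with genes past an FDR of 0.05 in both in colour. All 601 such genes had the same sign in both assays. The fitted values of genes with an arm at 0 depend on the prior count.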

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

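The predictions for the 3 patterns weighed below were written before their tests ran, and the tests on random splits of the libraries were chosen after the results were seen. The response to GDF9 differed between the R numbers in 3142 genes, by the interaction test of the single-cell fit. Among genes named by the rule, the adjusted p of this difference was 0.00595 for Fabp7, 0.00643 for Nnat, 0.00813 for Stmn3, 0.00828 for Msi1, 0.00921 for Otx2, 0.0108 for Gap43 and 0.0119 for Pou5f1. It was 0.0135 for Id3, 0.0142 for Spink1, 0.0148 for Uhrf1, 0.0164 for Ube2c, 0.0188 for Hey1, 0.0211 for Igfbp7, 0.0243 for Ankrd37 and 0.0264 for Id1. For Gata2, Smad7, Tpm2, Vcl, Upk3b and Thbd it was 0.0286, 0.0293, 0.0330, 0.0330, 0.0367 and 0.0374. For Stmn2, Pantr1, Dppa5a, Foxa2, Col1a1, Sox2, Dnmt3l and Cxcl5 it was 0.0387, 0.0392, 0.0392, 0.0402, 0.0406, 0.0420, 0.0472 and 0.0492.

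In bulk the response at 1.0 µg/ml differed from that at 0.1 µg/ml in 151 genes, by the test of the difference itself. The adjusted p was 0.00214 for Spink1, 0.0143 for Dmbx1, 0.0143 for Srgn, 0.0220 for Irs3, 0.0303 for Otx2 and 0.0318 for Nefl. It was 0.0324 for Stard13, 0.0368 for Syt8, 0.0391 for Tox3 and 0.0442 for Il17rb.

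The first pattern was that 6395 genes changed over all cells and at most 288 within a class. If fewer counts alone were the reason, the all-cell change would be kept within a class. The highest median kept was 44.0%, and leaving out R1 raised it to 59.3%. In T2 the medians ran from 24.3% in pluripotent-like to 28.8% in epithelial-or-keratinocyte-like cells. These values argue against fewer counts as the only reason, for the genes compared in the tested classes. A part played by fewer counts stayed open. Here the share of a class was its share of a library's UMIs, and each unnamed cluster of T2 was a class of its own. These shares applied to fixed class profiles gave a median of 77.2% of the all-cell change in T2, above the 75% written beforehand. It was 70.5% without R1, 83.7% without R3 and 74.1% without R4. A shift in the UMI shares of the classes could therefore give most of the all-cell change in T2, although the fixed profiles come from the same cells.

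The second pattern was that the median log2 fold change of trophoblast markers was -0.67 in pluripotent-like, -1.14 in stromal-like and -0.43 in epithelial-or-keratinocyte-like cells. The list was called in the first 2 with a preset correlation and in none with an estimated one. Free RNA from trophoblast-like cells would bring all markers into a class at about the same fraction of their level there. Over 14 markers the quartile ratio of these fractions was 1.43 in stromal-like cells (95% bootstrap 1.12 to 2.03) and 1.90 in epithelial-or-keratinocyte-like cells (1.32 to 2.78). Both ratios lay under the limit of 2 written beforehand, and both intervals cross it. It was 4.04 in pluripotent-like cells (95% bootstrap 1.39 to 8.62), above the limit of 4 written beforehand. By that rule alone free RNA was argued against, but the interval spans both limits, so free RNA stayed open. The medians were 5.12%, 4.52% and 5.43% in pluripotent-like, stromal-like and epithelial-or-keratinocyte-like cells. A cap on these fractions was dropped, and the bootstrap added, after the values were seen. Doublets were argued against, since without the cells with the highest scores the medians were -0.64, -1.60 and -0.43, and the removal took away -22.9% of the median fall of the 3 classes together, that is, the fall grew. Only the stromal-like fall grew by itself, and these scores may not hold all doublets. No empty droplets were analysed here, which keeps a real change within these classes open.

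The third pattern was that the difference between R numbers rested on R2. Across genes, the change specific to R2 correlated with the difference between sets T1 and T2 with a Spearman's rho of 0.289, between the limits of 0.1 and 0.3 written beforehand. Taken from GDF9 R1, control R1 and GDF9 R3 alone it was 0.506, 0.356 and -0.0627, on both sides of the limits, so the technical sets stayed open. With every library thinned to 965799 UMIs, 1544 of 10156 genes tested still differed, against 3142 of 15774. This lies between the limits of 25% and 50% of the full count that were written beforehand, and it leaves low UMIs in the R2 controls open. A different response of the R2 cultures could not be tested, because 0 libraries of R2 lie in T2. It would take GDF9 and control libraries of R2 made in 1 set to separate these.

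Random splits of the same libraries between the arms gave at most 160 genes in 100 splits for the all-cell comparison, against 6395. This argues against chance where the libraries are independent replicates. The splits mixed libraries of different R numbers, so they cannot exclude chance where R is the unit. In 100 splits no other reached the real count in stromal-like cells (at most 22, against 64) or in trophoblast-like cells (at most 28, against 62). For pluripotent-like cells 2 of 100 splits, the real one included, called at least 54 genes, and the highest other called 115. For epithelial-or-keratinocyte-like cells 4 of 100 called at least 288, and the highest other called 804. Both shares are below 0.05, but they were not adjusted over the classes, and more splits were added after earlier ones had been seen. They therefore do not exclude chance here. The splits that reached these counts followed the technical sets. The 1 in pluripotent-like cells parted the T1 libraries 6 to 1, as the real arms do, and the 3 in epithelial-or-keratinocyte-like cells parted them 6 to 0, 5 to 1 and 5 to 1, where the real arms have 5 to 1. The technical sets therefore stay open for these counts, and in T2 alone 8 and 166 genes were called. The real arms of stromal-like and trophoblast-like cells also part the T1 libraries 6 to 1, so the sets stay open there too. For the difference between R numbers, 1 of 30 exchanges of R numbers within each arm, the real one included, reached 3142 genes and the highest other 457. These exchanges also remove the differences between R numbers that both arms share, so they do not test an equal response. For the difference between doses 7 of 50 splits, the real one included, called at least 151 and the highest other called 445. The 6 others kept or exchanged the arms at 1.0 µg/ml whole, and with these arms mixed the highest was 1. Splits that keep these arms whole also keep the response at 1.0 µg/ml. The share of splits therefore cannot decide on chance for the dose difference, and chance was not excluded. With 10 splits there are too few for a share below 0.05. There the real and highest other counts were 5657 and 7 in R1, 6755 and 0 in R2, 2346 and 1490 in R3 and 2394 and 0 in R4. In bulk they were 108 and 6 at 0.5 µg/ml, 743 and 7 at 1.0 µg/ml and 1 and 0 for the controls. At 0.1 µg/ml all 10 splits reached the real count of 0, and the highest other was 1.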

How the results depend on the processing

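No result past its threshold both in the main analysis and under an alternative reversed its direction, while 24 gene list tests and 92 values of named genes changed sign with neither side past it. Of 608 gene list tests under alternatives, 471 kept their side of the threshold, 123 were weaker and 14 stronger. Of 5318 values of named genes, 4760 kept their side, 506 were weaker and 52 stronger. The all-cell count of 6395 stayed within a factor of 1.5 under DESeq2, RLE scaling, library size alone, no filter, other cell filters, removal of the highest doublet scores and T2 alone, and lay from 4436 to 6710 when 1 R number was left out. The settings for technical sets, for the libraries of low depth, for clusters of all cells together, for unnamed clusters and for the highest doublet scores were chosen after seeing the data. The cause was not tested for any change below. Depth limits which genes were seen: the bulk libraries with 37046 and 88391 counts had a count in 6181 and 7858 genes, and the others in 8690 to 13297.

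With UMIs summed per R number, 4 against 4, the all-cell comparison called 1334 genes, and 3141 when R was also a block. With only the 6 libraries of an R number in the fit, R1 had 3133, R3 had 10 and R4 had 7597 genes. T2 alone gave 6696 for R4. Leaving out 1 library gave 693 to 5116 for R3 and 1068 to 1384 for R4. The difference between R numbers had 1 to 3874 genes when 1 R number was left out, with 1 without R2, and 10 in T2 alone.

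For the classes, DESeq2 called 368 genes in pluripotent-like, 165 in stromal-like, 588 in epithelial-or-keratinocyte-like and 274 in trophoblast-like cells. With no filter the counts were 194, 245 and 787 in pluripotent-like, stromal-like and epithelial-or-keratinocyte-like cells. In T2 alone they were 8, 36, 166 and 32. Leaving out 1 R number gave 0 to 346 in pluripotent-like, 14 to 173 in stromal-like, 93 to 1107 in epithelial-or-keratinocyte-like and 0 to 137 in trophoblast-like cells.

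The block designs treat R and C numbers as pairs. In the pairing check the means of R1, R2, R3 and R4 correlated between the arms by 0.438, 0.0705, 0.116 and 0.583. The numbered single-cell pairs ran from -0.293 to 0.616 and the bulk pairs from -0.0552 to 0.0870, and not every library correlated best with its own number. With C as a block R3 had 896 and R4 had 1181 genes. With R as a block pluripotent-like cells had 151, stromal-like 147 and trophoblast-like 199 genes. With permutation within R numbers all 6 class shares kept their call, with adjusted p from 7.5e-05 to 0.00386.

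For class shares, R numbers as the unit (4 against 4, exact permutation) gave differences of 16.1 percentage points for pluripotent-like (adjusted p = 0.200), -13.4 for stromal-like (0.129), -11.0 for epithelial-or-keratinocyte-like (0.114) and -19.0 for trophoblast-like cells (0.0857). Neural-progenitor-like cells had 12.5 (0.137) and neuron-like cells 6.50 (0.0857). The pluripotent-like difference was 12.7 at a resolution of 2.0 (permutation p = 0.0761 after adjustment), 6.49 with clusters from all cells together (0.477) and 17.5 in T2 with cells thinned and picked by marker UMIs (0.106). Leaving out 1 R number gave 10.1 (without R3, 0.110) to 23.3, with 15.0 without R4 (0.118). It was 13.0 in T2 without GDF9 R3_C3 and control R3_C1 (0.0593) and 8.61 without GDF9 R3_C1, GDF9 R3_C3 and control R3_C1 (0.126). The stromal-like difference was -13.3 in T2 (exact permutation p = 0.0856 after adjustment), -14.8 in T2 without the same pair of libraries (0.0593) and -11.1 with clusters from all cells together (0.0562). The epithelial-or-keratinocyte-like difference was -1.85 at a resolution of 2.0 (permutation p = 0.547 after adjustment), -8.50 with clusters from all cells together (0.0562) and -3.77 with unnamed clusters counted by their leading markers (0.357).

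In bulk, no filter gave 207 genes at 0.5 µg/ml, 250 for the dose difference and 6 between the controls, and RLE scaling gave 0 between the controls. With only the 6 libraries of a dose in the fit, 0.5 µg/ml had 372 and 1.0 µg/ml had 457 genes, and against all 9 controls they had 316 and 1773. DESeq2 called 308 at 0.5 µg/ml. Without the 3 libraries under 400000 counts, 0.5 µg/ml had 360 genes and the dose difference 232. Leaving out 1 library gave 0 to 1 at 0.1 µg/ml, 22 to 122 at 0.5 µg/ml, 380 to 735 at 1.0 µg/ml, 36 to 206 for the dose difference and 0 to 1 between the controls.

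With an estimated correlation the lists called dropped from 14 to 0 over all cells, from 16 to 2 in R1, from 10 to 0 in R2, from 12 to 0 in R3 and from 13 to 2 in R4. Within classes they dropped from 6 to 1 in pluripotent-like, from 5 to 0 in stromal-like, from 8 to 1 in epithelial-or-keratinocyte-like and from 6 to 0 in trophoblast-like cells. In bulk they dropped from 2 to 0, 5 to 0 and 12 to 4 at the rising doses, from 12 to 0 for the dose difference and from 2 to 0 between the controls. With the mean of the 3 dose contrasts, 98.6% of the genes called in both assays had the same sign, with a Spearman's rho of 0.512.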

Other observations

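Nkx6-1, Shh and Nkx6-2 were higher with GDF9 and were picked out after their values were seen, with no test of them as a group. Nkx6-1, a homeobox gene of the ventral neural tube, stood at 3.60 ± 1.76 CPM (SD, n = 12) against 0.0562 ± 0.106 in the single-cell libraries (edgeR FDR 3.6e-08). Shh, the signal made by the floor plate, stood at 5.05 ± 4.16 CPM against 0.0365 ± 0.0998 (edgeR FDR 2.8e-07). Nkx6-2 rose by 4.25 on the log2 scale (edgeR FDR 8.6e-06).

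An unnamed cluster of T2, number 7, held 10.8% of GDF9 cells and 1.06% of control cells (exact permutation p = 0.00200, two-sided, chosen after its values were seen). Its leading genes included Spink1, Actc1, Trh and Rbp4. An unnamed cluster of T1, number 13, with Spon1, Vtn, Foxa2 and Shh among its leading genes, held 2.73% of GDF9 cells and 0 cells of the single T1 control. An unnamed cluster of T2, number 10, which leads in trophoblast markers, held 2.56% of GDF9 cells and 7.58% of control cells (exact permutation p = 0.0170).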
